A study of Drosophila melanogaster with 16 samples.

How the data were processed

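Total RNA of 16 libraries from female larvae was sequenced, 4 libraries for each of 4 groups: fat body or fat body with ovaries, from heterozygotes or from animals labelled homozygous for dLmx1a delta1. Groups were taken from the titles of the samples. The deposited columns name the libraries titled heterozygous WT and those titled homozygous M. The genotype field of the samples labelled homozygous counts up the allele number from sample to sample, and their titles were followed instead.

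Reads were trimmed with Trimmomatic 0.36, aligned to dm6 with STAR 2.5.2b and counted per gene with featureCounts of Subread 1.5.0p3, per the submitters' processing notes. The strand setting of the counting, the gene annotation and the handling of reads with several hits are not given in the sources used here. Near-identical copies such as LysX and its neighbours or the GstD and Tot families, and genes that overlap on opposite strands, are therefore uncertain. The deposited table gives the signal of 16727 genes in each library as gene counts divided by a size factor for that library, and its name gives DESeq2 as the normalising tool. The values were not rounded, and 100% of the values above 0 were whole multiples of the value of 1 read in their library, within a tolerance of 1e-06 (largest deviation 2.14e-08). In 2 of the 16 libraries (fat body labelled homozygous replicate 4, and heterozygous fat body with ovaries replicate 1) the value of 1 read lies so close to 1 that the automatic test of such steps makes no judgement, and whole reads there rest on the direct division alone. Size factors computed here with DESeq2 on the recovered reads equalled the deposited ones. A library's value of 0 allows up to 3 reads, which is the limit printed beside it, and such limits and intervals cover counting error only, since reads copied by PCR are not independent molecules. The 6 fat body genes whose share of the counts is given are Fbp1, Fbp2, Lsp1alpha, Lsp1beta, Lsp1gamma and Lsp2.

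Before the data were examined, the groups, comparisons, tests, thresholds, 22 gene lists, the rule for named genes and the alternative settings were fixed, except for those said to be chosen later. Genes with a mean of at least 10 normalised counts over the 16 libraries were kept (7824). Values were taken to log2 after adding 1 and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 16 libraries, an intensity trend and moderated variances. Tests were 2-sided with Benjamini-Hochberg adjustment over all kept genes at 0.05. The 5 contrasts were fat body with ovaries against fat body in each genotype, the libraries labelled homozygous against the heterozygous ones in each tissue, and the interaction, which is the tissue contrast of the libraries labelled homozygous minus that of the heterozygotes. Folds are log2 with the limma standard error, and group values are means of normalised counts with their SD. Ovary-enriched genes are those past the threshold and at least 1 log2 unit higher with ovaries in heterozygotes. Coordinates and chromosomes came from the Release 6 reference table, the assembly that dm6 names, in which 16445 of the 16727 symbols and 7722 of the 7824 kept genes were placed.

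The gene lists cover germline, terminal filament and cap cells, other ovarian somatic cells, fat body, adhesion and cytoskeleton, basement membrane, ecdysone response, immune genes, cell cycle, the Notch, BMP and JAK/STAT pathways, heat shock and stress, cytosolic ribosomal proteins, and markers of salivary glue, hemocytes, muscle, gut, neurons, trachea, cuticle and testis as tissues that dissection might carry along. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move on balance to 1 side without comparing them with other genes. Adjustment ran over the 22 lists within a contrast. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. Named genes are dLmx1a, the 10 named symbols with the largest positive and the 10 with the largest negative fold in each contrast among those past the threshold with a mean of at least 50 in the higher group and no overlap between groups, the 5 largest folds whatever the symbol, and up to 4 members of each list with the smallest p past the threshold (or the 1 smallest when none passed). The text leaves out some of these and adds CR32207. Positions of called genes on arms 3L and 3R were compared with Fisher's exact test.

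Whether equal replicate numbers pair libraries was checked by correlating the deviations from group means across genes. Between fat body with and without ovaries the same-number correlations were 0.284, 0.015, 0.04 and 0.225 in heterozygotes and 0.61, 0.424, 0.198 and 0.476 in the libraries labelled homozygous. Between genotypes they were 0.253, 0.417, 0.173 and 0.415 with ovaries and 0.676, 0.385, 0.291 and 0.213 in fat body. The number paired the libraries in each case except between the tissues of heterozygotes, where only replicates 1 and 4 matched best with their own number. Total calls with the replicate number as a block are given for each contrast, and so are some results of gene lists. Adjusted p-values of named genes and the fits that leave out a library come from the model without the block. These correlations run across genes, which are not independent replicates.

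The alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50, TMM factors, equal library totals, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on recovered reads, the replicate block, array weights, robust variances, leaving out each library, only the 8 libraries compared, a fold of at least 2 log2 units for ovary-enriched genes, a set of these chosen on replicates 1 and 2, and calls of at least 1 log2 unit for the chromosome test. Chosen after seeing the data were the fits without heterozygous fat body replicate 2 and replicate 1 of the fat body labelled homozygous, the chromosome test under all of the above settings, and the counts of list members under the block and without those libraries. The pipeline was tested on simulated counts of the 7824 genes, with 100 genes changed at each fold size. Of genes changed by a fold of 2 limma recovered 71% in the heterozygote tissue contrast, 67% in that labelled homozygous, 67% between genotypes with ovaries, 68% between genotypes in fat body and 42% in the interaction. For a fold of 4 the shares were 87%, 90%, 86%, 88% and 78%, and 8, 5, 5, 14 and 8 unchanged genes were called. The simulated genes were drawn independently, with as many raised as lowered. Apart from these changes a gene had the same mean level in all groups, so genes read almost only with ovaries were not simulated. The simulated counts also held no pairing of replicates, no library that stands apart and no shift of composition. The recovered shares therefore do not cover such genes or such features of the real data.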

Results

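RNA was sequenced from female Drosophila melanogaster at the transition from the third larval stage to the prepupa. The tissue was either larval fat body, the larval organ of storage and metabolism, or fat body together with the developing ovaries that lie within it. The animals were either heterozygous for the delta1 allele of dLmx1a over the balancer TM3-GFP or labelled homozygous for it, and each of the 4 combinations of tissue and genotype had 4 libraries. dLmx1a encodes a LIM homeodomain transcription factor, and the sources used here give the comparison of these genotypes in the developing ovary as the purpose. The 16 libraries held between 19022106 reads (fat body labelled homozygous, replicate 1) and 32755588 reads (fat body labelled homozygous, replicate 3) counted on genes. Between 10105 and 10970 genes had a read in a library, and 6 fat body genes together took 49.7% to 58.7% of the normalised counts. The first principal component carried 63.5% of the variance and separated the tissues, while on the second, with 11.7%, replicate 1 of the fat body labelled homozygous stood furthest out at 59.3. Nothing in the labels says that the replicates came from separate groups of animals, so the p-values measure the spread between these libraries.

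dLmx1a itself (CG32105, arm 3L, 12329232 to 12335901 of dm6) was read at high level wherever ovaries were present. Its normalised counts were 578, 518, 723 and 649 in the 4 heterozygous libraries with ovaries and 564, 671, 742 and 682 in the 4 libraries with ovaries labelled homozygous. In heterozygous fat body they were 2.83, 23.5, 1.11 and 0, where 0 reads allow up to 3.22, and in fat body labelled homozygous they were 4.59, 0, 0.974 and 0, where 0 reads allow up to 3.64 and 2.99. The log2 fold between tissues was 7.35 ± 0.75 (SE, n = 4 per group, adjusted p = 2.76e-06) in heterozygotes and 8.51 ± 0.75 (adjusted p = 5.49e-07) in the libraries labelled homozygous. Between genotypes it was 0.11 ± 0.75 with ovaries (adjusted p = 0.984) and -1.04 ± 0.75 in fat body (adjusted p = 0.489), so CG32105 RNA was not detectably lower in libraries labelled homozygous. This SE is drawn from all 16 libraries, including fat body libraries with few reads. It does not describe the spread among the libraries with ovaries alone. There the counts of the genotypes overlapped, at 518 to 723 in heterozygotes and 564 to 742 in those labelled homozygous. These counts cover the whole gene, and the part that delta1 removes is not given in the sources used here, so they do not check the genotype labels. The gene w, which encodes a transporter of eye pigment precursors, did follow the labels, at 41.5 to 202 normalised counts in the heterozygous libraries and 0 to 3.06 in those labelled homozygous. Only the heterozygotes are given as carrying TM3-GFP, so w cannot tell the balancer from delta1.

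**Figure D1:**
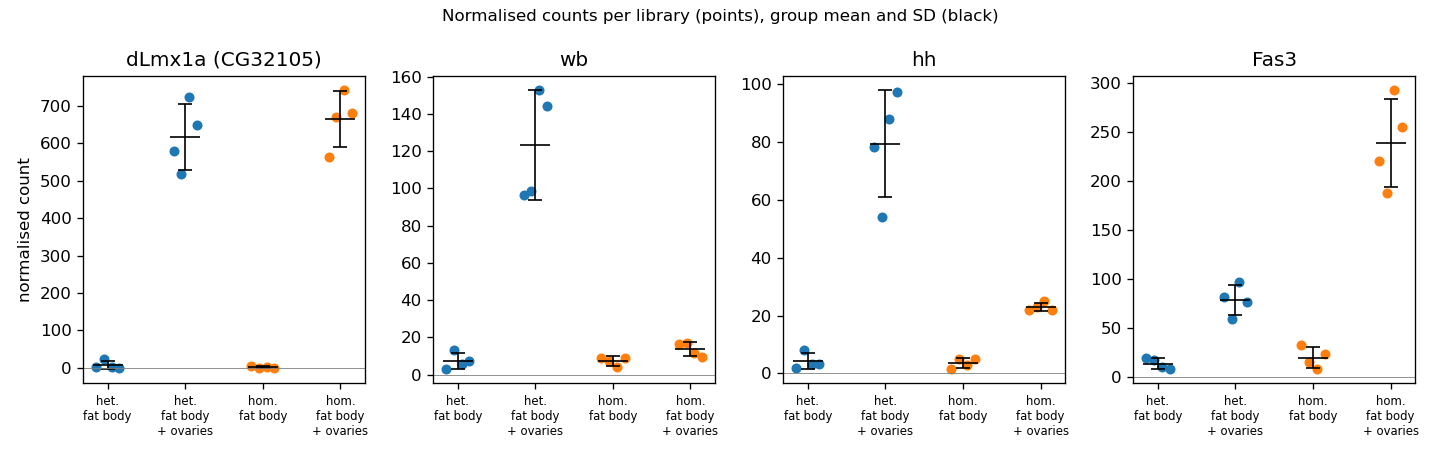
Normalised counts of dLmx1a, wb, hh and Fas3 in each of the 16 libraries, by tissue and genotype, with the mean and SD of each group of 4. dLmx1a stands at 518 to 742 in every library with ovaries, whereas wb stands at 96.6 to 153 in heterozygous libraries with ovaries and at 9.42 to 17.2 in those labelled homozygous.

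The comparison of tissues within heterozygotes asked which transcripts the developing ovary adds to the fat body. Germline genes rose together, with piwi, an Argonaute gene of the piRNA pathway, going from 14.9 ± 26.3 to 1147 ± 179 normalised counts (SD, n = 4 per group, log2 fold 7.83 ± 0.83, SE, adjusted p = 4.13e-06). vas, which encodes a germline RNA helicase, went from 13.8 ± 14.1 to 556 ± 103 (log2 fold 5.62 ± 0.43, adjusted p = 2.80e-07), and bgcn, needed for germ cell differentiation, rose by 4.53 ± 0.29 on the log2 scale. Of 25 measured germline genes 24 rose and 1 fell (camera adjusted p = 7.19e-18, and adjusted p = 0.0257 with an estimated correlation). Genes of the terminal filament and cap cells, which form the germline stem cell niche, rose in 8 of 10 cases (camera adjusted p = 1.12e-06, and adjusted p = 0.0257 with an estimated correlation). They included bab1, a transcription factor gene of terminal filament cells (4.64 ± 0.38), nord (4.89 ± 0.30) and ptc, the gene of the Hedgehog receptor (2.88 ± 0.18). Of 16 genes of other ovarian somatic cells 11 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.12e-06, and adjusted p = 0.0257 with an estimated correlation). Among them was the signalling ligand gene Wnt4 at 7.33 ± 0.68. Cell cycle genes rose in 25 of 27 cases (26 adjusted over the list alone, camera adjusted p = 7.19e-18). CycA, the cyclin A gene, stood at 3.60 ± 0.18, the Cdc25 phosphatase gene stg at 4.16 ± 0.30 and the mitotic kinase gene polo at 6.95 ± 0.77. With an estimated correlation that list stood at adjusted p = 0.0507. In the Notch pathway list 7 of 11 genes rose (camera adjusted p = 0.00161, and adjusted p = 0.149 with an estimated correlation). Adhesion and cytoskeleton genes rose in 12 of 27 cases (13 adjusted over the list alone, camera adjusted p = 0.0255, and adjusted p = 0.418 with an estimated correlation). Among them were the cell adhesion genes ed (4.48 ± 0.50) and Fas2 (2.34 ± 0.26).

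Fat body transcripts were on balance lower where ovaries were present in heterozygotes, in units of the deposited normalisation. Of 23 measured fat body genes 6 fell and 0 rose (camera adjusted p = 0.0116, and adjusted p = 0.224 with an estimated correlation). They included srp, the GATA factor gene of the fat body, at -0.46 ± 0.11 and Mtp, which is needed to assemble lipoproteins, at -0.42 ± 0.09. When every library was scaled to the same total, 1 of the 23 rose, 0 fell, and the calls of srp and Mtp ended. Antimicrobial and immune genes fell in 2 of 19 cases (1 adjusted over the list alone), with the peptidoglycan receptor gene PGRP-SA at -0.83 ± 0.14 (camera adjusted p = 0.0428, and adjusted p = 0.349 with an estimated correlation). That list's call also ended with the replicate number as a block and without the pair of fat body libraries that stood apart, heterozygous replicate 2 and replicate 1 of those labelled homozygous. The ribosomal protein list was called lower by camera (adjusted p = 0.00422, and adjusted p = 0.874 with an estimated correlation). Of its 86 genes 3 were higher and 1 lower, with a median of -0.11 and a mean of 0.08. The call ended with fry (adjusted p = 0.402) and without the same pair of libraries, and at equal totals 66 of the genes rose and 0 fell. The other 13 lists passed no camera threshold in this contrast (adjusted p from 0.297 to 0.888). Their genes higher and lower were 3 and 5 of 13 for basement membrane, 4 and 1 of 20 for the ecdysone response, and 3 and 1 of 14 for the BMP pathway. They were 2 and 1 of 6 for JAK/STAT and 2 and 2 of 13 for heat shock and stress. For markers of other tissues these numbers were 0 and 0 of 6 for salivary glue, 0 and 3 of 12 for hemocytes, 0 and 2 of 13 for muscle and 0 and 1 of 5 for gut. They were 1 and 0 of 7 for neurons, 1 and 1 of 8 for trachea, 0 and 1 of 6 for cuticle and 1 and 0 of 5 for testis and male genes. Adjusted over the list alone they were 4 and 0 for the ecdysone response and 4 and 1 for the BMP pathway, with the others unchanged. With fry the testis and male list was called higher (adjusted p = 0.00104), and its member past the threshold was mia at 2.05 ± 0.33. In all, limma called 2295 of 7824 genes, 1458 higher and 837 lower. At equal totals 3433 were higher and 64 lower, because that scaling moved the median log2 fold of all genes from -0.05 to 0.34. In fat body replicate 2 of the heterozygotes the germline genes stood at a median of 7.96% of their level with ovaries, against at most 3.46% in the other 7 fat body libraries.

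The same comparison in the libraries labelled homozygous asked what the ovary adds in animals labelled homozygous for delta1. Germline genes rose in 23 of 25 cases and 1 fell (camera adjusted p = 5.50e-17, and adjusted p = 0.0374 with an estimated correlation). piwi went from 1.81 ± 0.94 to 1172 ± 116 normalised counts (SD, n = 4 per group, log2 fold 8.76 ± 0.83, adjusted p = 1.10e-06), and vas rose by 6.61 ± 0.43 on the log2 scale. Niche genes rose in 7 of 10 cases (camera adjusted p = 5.38e-06, and adjusted p = 0.0374 with an estimated correlation), with bab2, the paralogue of bab1, at 7.91 ± 0.61. Other ovarian somatic genes rose in 11 of 16 cases and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 6.10e-06, and adjusted p = 0.0374 with an estimated correlation). Wnt4 stood at 8.72 ± 0.68 and the adhesion gene Fas3 at 3.71 ± 0.36. Cell cycle genes rose in 26 of 27 cases (camera adjusted p = 5.50e-17, and adjusted p = 0.0594 with an estimated correlation). CycA stood at 4.78 ± 0.18 and the mitotic kinesin gene pav at 7.13 ± 0.37. Notch genes rose in 6 of 11 cases (camera adjusted p = 0.00292, and adjusted p = 0.192 with an estimated correlation). Adhesion genes rose in 11 of 27 (12 adjusted over the list alone), among them the polarity gene baz at 3.49 ± 0.31 (camera adjusted p = 0.0151, and adjusted p = 0.399 with an estimated correlation). Of 23 fat body genes 6 fell and 1 rose, with srp at -0.73 ± 0.11 (camera adjusted p = 0.0151, and adjusted p = 0.262 with an estimated correlation). At equal totals 1 fell, 1 rose and the list's median was 0.08. Ribosomal protein genes were called lower by camera (adjusted p = 0.000112, and adjusted p = 0.726 with an estimated correlation). Of 86 genes 4 were higher and 2 lower, with a median of -0.17 and a mean of 0.06. The call ended with fry (adjusted p = 0.154), and at equal totals 67 rose. The other 14 lists passed no camera threshold in this contrast (adjusted p from 0.173 to 0.781), but fry called 4 of them. Markers of testis and male genes were called higher (fry adjusted p = 0.000154), with 2 of 5 genes past the threshold, mia at 1.99 ± 0.33 and achi at 0.65 ± 0.15. Neuronal markers were called higher (fry adjusted p = 0.0183), with 2 of 7 genes past it, Snap25 at 3.38 ± 0.52 and elav at 1.76 ± 0.35 (2 higher and 1 lower adjusted over the list alone). Gut markers were called lower (fry adjusted p = 0.0121) with 0 of 5 genes past it. The BMP list was called higher (fry adjusted p = 0.0244), with 5 of 14 genes higher and 1 lower (5 and 2 adjusted over the list alone), among them the glypican gene dlp at 3.71 ± 0.30. In the other 10 lists the genes higher and lower were 2 and 7 of 13 for basement membrane, 3 and 0 of 20 for the ecdysone response, and 0 and 1 of 19 for immune genes. They were 2 and 1 of 6 for JAK/STAT and 2 and 2 of 13 for heat shock and stress. For markers of other tissues they were 0 and 0 of 6 for salivary glue, 0 and 1 of 12 for hemocytes, 1 and 3 of 13 for muscle, 1 and 1 of 8 for trachea and 0 and 1 of 6 for cuticle. Adjusted over the list alone they were 2 and 2 for JAK/STAT, 1 and 4 for muscle and 1 and 0 for trachea, with the others unchanged.

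Most of the genes higher with ovaries were called in both genotypes. Of 1458 genes higher in heterozygotes and 1547 higher in the libraries labelled homozygous 1294 were shared, against 288 for independent calls, and of 837 and 1032 lower genes 613 were shared, against 110. No gene was called in opposite directions (0). The contrasts share no library, but both take each gene's variance from the same fit over all 16 libraries. Their calls are therefore not independent. Of the genes at least 1 log2 unit higher, 839 in heterozygotes and 907 in the libraries labelled homozygous, 774 were in both sets. In the libraries labelled homozygous limma called 2579 of 7824 genes, 1547 higher and 1032 lower, and 3759 with the replicate number as a block. At equal totals 3634 were higher and 39 lower, with the median log2 fold of all genes at 0.37 instead of -0.05. The camera calls of the fat body and adhesion lists in this contrast ended without the pair of fat body libraries that stood apart.

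The comparison of genotypes in fat body with ovaries asked which transcripts differ in animals labelled homozygous where the developing ovary is present. These libraries also hold fat body. Of the genes called here, 51 of the 72 higher and 72 of the 93 lower were called in the same direction in fat body alone. wb, which encodes a laminin alpha chain of basement membranes (arm 2L, 14263027 to 14328262 of dm6), was lower in all 4 libraries labelled homozygous. It stood at 13.6 ± 3.69 against 123 ± 29.6 normalised counts (SD, n = 4 per group, log2 fold -3.09 ± 0.37, SE, adjusted p = 0.000314). hh, the gene of the Hedgehog ligand that niche cells secrete (arm 3R, 23128169 to 23141906), was lower at 22.9 ± 1.42 against 79.5 ± 18.6 (log2 fold -1.72 ± 0.36, adjusted p = 0.0234). Fas3, an adhesion gene of epithelia and ovarian somatic cells (arm 2L, 18320102 to 18393441), was higher at 239 ± 45.2 against 78.5 ± 15.6 (log2 fold 1.60 ± 0.36, adjusted p = 0.0384). The Toll-8 receptor gene Tollo (1.30 ± 0.18, adjusted p = 0.00103), the deacetylase gene Sirt2 (0.96 ± 0.13) and the mitochondrial ribosomal protein gene mRpL9 (0.94 ± 0.12) were also higher. The largest folds among the named genes were lower values in the libraries labelled homozygous, led by CG11893 on arm 3R (2.77 ± 1.56 against 2417 ± 947, log2 fold -9.35 ± 0.35, adjusted p = 5.79e-10). CG42326 (-6.46 ± 0.51), the lysozyme gene LysX (-6.35 ± 0.65), w (-6.04 ± 0.49), the myosin light chain gene Mlc2 (-4.06 ± 0.49) and the cytochrome P450 gene Cyp6d5 (-3.73 ± 0.24) were lower as well.

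In the fit over all 16 libraries, few genes of the ovarian lists passed the test between these genotypes. Of 25 germline genes 0 passed, of 27 cell cycle genes 0, of 11 Notch genes 0, of 10 niche genes 1 (hh), of 16 other ovarian somatic genes 1 (Fas3) and of 13 basement membrane genes 1 (wb). These counts are from the fit without the replicate number as a block. With the block limma called more genes in this contrast (660 in place of 165), and list counts with the block are not given here. With only the 8 libraries compared in the fit it called 229, of which 134 were among the 165. The main fit takes a gene's spread from all 16 libraries, including fat body libraries with few reads of ovarian genes. The low counts therefore do not show that these lists are unchanged. At an unadjusted p under 0.05 limma called 1054 genes in this contrast, and edgeR and DESeq2 called 155 and 416 after adjustment. Ribosomal protein genes shifted upward as a list (median 0.26, camera adjusted p = 2.57e-29, and adjusted p = 0.66 with an estimated correlation), a call that ended with fry (adjusted p = 0.0579). Of the 86 genes 3 passed over all genes and 53 adjusted over the list alone. The former count was 0 with equal totals, 0 with edgeR and 0 without heterozygous fat body replicate 2. Salivary glue genes were called higher by camera (adjusted p = 0.0305, and adjusted p = 0.777 with an estimated correlation) with 0 of 6 genes past the threshold. That call ended with fry (adjusted p = 0.471) and without the pair of fat body libraries that stood apart. Their sum was 3347 normalised counts in replicate 2 of the libraries with ovaries labelled homozygous against at most 137 in the other 3. Gut markers were called lower with fry (adjusted p = 0.0109) but not with camera (adjusted p = 0.0858), with 1 of 5 genes past the threshold, LysX. Each of the other lists had at most 2 members past the threshold and no camera call (adjusted p from 0.0858 to 0.995). limma called 165 of 7824 genes, 72 higher and 93 lower, and 660 with the replicate number as a block. At equal totals 52 were higher and 156 lower, with the median log2 fold of all genes at -0.07. Leaving out any 1 of the 8 libraries compared lowered the count to between 60 and 103, and leaving out replicate 1 of the fat body labelled homozygous raised it to 264. The wb, Tollo, Sirt2 and mRpL9 calls held in all 16 such fits. The call of Fas3 ended without any 1 of the 8 libraries compared (adjusted p up to 0.11), while its fold stayed between 1.47 and 1.71. The call of hh ended without heterozygous replicates 1, 3 or 4 or any replicate labelled homozygous, all with ovaries (adjusted p up to 0.0867). The fold of hh stayed between -1.89 and -1.61.

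The comparison of genotypes in fat body alone asked which differences the genotypes carry outside the ovary, the TM3-GFP balancer included. CG11893 was again near 0 in the libraries labelled homozygous, at 3.24 ± 1.25 against 1860 ± 572 normalised counts (SD, n = 4 per group, log2 fold -8.78 ± 0.35, SE, adjusted p = 1.42e-09). Lower as well were w (-4.67 ± 0.49), Mlc2 (-3.78 ± 0.49) and Cyp6d5 (-3.72 ± 0.24). Cks85A, which encodes a subunit of cyclin-dependent kinases, was lower at 23.9 ± 2.56 against 120 ± 33.4 (log2 fold -2.25 ± 0.17, adjusted p = 2.27e-06). The same direction held for hdly at -2.20 ± 0.20, the piRNA Argonaute gene AGO3 at -1.49 ± 0.23 and CycA at -1.23 ± 0.18. Higher were HipHop, a telomere capping gene (98.8 ± 8.95 against 43.9 ± 11.8, log2 fold 1.19 ± 0.16, adjusted p = 0.000698), Sirt2 (1.06 ± 0.13), Tollo (0.96 ± 0.18) and the insulator gene CTCF (0.79 ± 0.10). Ribosomal protein genes rose in 25 of 86 cases and 1 fell (77 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 6.03e-28, and adjusted p = 0.742 with an estimated correlation). That count was 72 with the replicate block, 12 with TMM factors, 9 with edgeR, 1 at equal totals, 8 without heterozygous replicate 2 and 12 without replicate 1 of those labelled homozygous. Among germline genes 3 of 25 fell and among neuronal genes 2 of 7, but 1 of each without heterozygous replicate 2, in which germline genes stood at a median of 7.96% of their level with ovaries. The germline count was 2 without replicate 1 of those labelled homozygous. The call of the piRNA pathway gene qin, at -1.11 ± 0.26, ended without heterozygous replicate 2 or 4 or replicate 2 of those labelled homozygous (adjusted p up to 0.0639), without the pair of libraries that stood apart, with array weights and with only the 8 libraries compared. The neuronal list was called lower with fry (adjusted p = 0.0133) but not with camera (adjusted p = 0.349), and its 2 genes were Snap25 at -3.13 ± 0.52 and cpx at -1.09 ± 0.26. Each of the other lists had at most 1 member past the threshold, with no camera call in any list but the ribosomal one (adjusted p from 0.302 to 0.871).

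limma called 422 of 7824 genes between genotypes in fat body, 179 higher and 243 lower, and 1178 with the replicate number as a block. At equal totals 69 were higher and 427 lower, with the median log2 fold of all genes at -0.11. Without heterozygous fat body replicate 2, 3 or 4 the count was 245, 230 or 201, and without replicate 3 of those labelled homozygous it was 231. With only the 8 libraries compared in the fit it was 76, and AGO3, CycA and Tollo no longer passed. Of 72 and 179 genes higher in the libraries labelled homozygous with and without ovaries 51 were shared, against 1.65 for independent calls. Of 93 and 243 lower genes 72 were shared, against 2.89, with 0 in opposite directions. Both genotype contrasts take each gene's variance from the same fit, so their calls are not independent.

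The third chromosome, which carries dLmx1a and in heterozygotes the rearranged balancer TM3, held most of the genotype calls. With ovaries 118 of 163 placed genes (72.4%) lay on arms 3L or 3R, against 42.7% of the other tested genes (Fisher's exact test, 2-sided, odds ratio 3.52, 95% interval 2.47 to 5.09, p = 4.14e-14). In fat body alone 274 of 416 (65.9%) did, against 42.1% (odds ratio 2.66, Fisher's exact test, 95% interval 2.15 to 3.30, p = 2.96e-21). Among calls of at least 1 log2 unit the shares were 80.3% of 71 and 86.2% of 130. Tollo, Sirt2, mRpL9, hh, CG11893, LysX, Mlc2, Cyp6d5, Cks85A, hdly, AGO3, CycA, HipHop and CTCF lie there, while wb, Fas3 and CG42326 lie on the second chromosome and w on the X chromosome. These are places in the reference, and copies placed elsewhere in these animals were not looked for. In the comparisons of tissues the odds ratio by the same exact test was 1.10 in heterozygotes (p = 0.049) and 1.12 in the libraries labelled homozygous (p = 0.0202). Neighbouring genes are not independent, so these intervals cover counting error only.

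**Figure D2:**
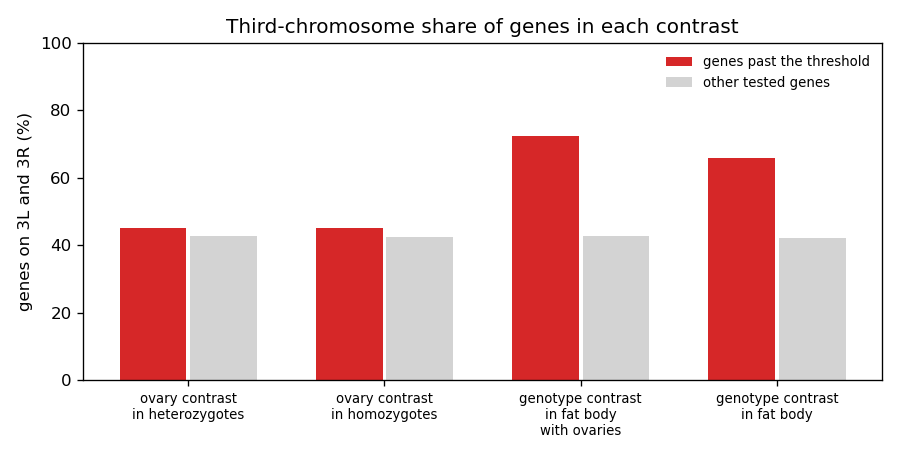
Percent of placed genes on arms 3L and 3R among genes past the threshold and among the other tested genes, for both comparisons of tissues and both comparisons of genotypes. The genes called between genotypes reach 72.4% with ovaries and 65.9% in fat body, against 42.7% and 42.1% of the other genes.

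The interaction asked whether the log2 fold between tissues differs between genotypes. Libraries with ovaries also hold fat body, so this fold depends on the fat body level as well as on what the ovary adds. A lower fat body level alone can therefore give a positive interaction. wb rose with ovaries from 7.31 ± 4.44 to 123 ± 29.6 normalised counts in heterozygotes. It stood at 7.34 ± 2.44 and 13.6 ± 3.69 in the libraries labelled homozygous (SD, n = 4 per group, interaction -3.20 ± 0.53, SE, adjusted p = 0.0478). Spc105R, a kinetochore gene, went from 24.4 ± 5.38 to 188 ± 38.2 in heterozygotes and from 4.68 ± 2.64 to 299 ± 38.6 in those labelled homozygous (interaction 2.97 ± 0.46, adjusted p = 0.0405). hdly passed as well (1.77 ± 0.28, adjusted p = 0.0405), as did the non-coding gene CR32207, which was chosen after its values were seen. hh (-1.60 ± 0.51, adjusted p = 1), Fas3 (1.18 ± 0.51, adjusted p = 1), CycA (1.18 ± 0.26, adjusted p = 0.238) and AGO3 (1.30 ± 0.32, adjusted p = 0.409) did not pass. Their genotype difference was not shown to depend on the tissue. Of the 22 lists 0 were called. Of 839 ovary-enriched genes, those at least 1 log2 unit higher with ovaries in heterozygotes, 3 passed in the interaction. Their median interaction was 0.11, within its SD over replicates of 0.47, and their median genotype fold with ovaries was 0.04 (SD over replicates 0.10), with 8 of them lower and 5 higher past the threshold in the libraries labelled homozygous. limma called 4 genes in the interaction, 3 positive and 1 negative, 182 at an unadjusted p under 0.05, and 0 with the replicate number as a block, while edgeR called 4, of which 3 were shared and wb was not among them, and DESeq2 20. The calls of Spc105R, hdly and CR32207 ended without any 1 library other than replicates 1, 2 and 3 of the fat body labelled homozygous (adjusted p up to 0.146). The call of wb ended without any 1 other than heterozygous replicate 2 and replicate 3 labelled homozygous, both of fat body (adjusted p up to 0.175). All 4 calls also ended at a pseudocount of 0.5, without a filter and at equal totals. The wb call further ended with TMM factors (adjusted p = 0.0512), edgeR (adjusted p = 0.0592) and robust variances (adjusted p = 0.0511). Those of hdly and CR32207 ended without the pair of fat body libraries that stood apart (adjusted p = 0.0546 and 0.0629), that of CR32207 at a pseudocount of 5, and those of Spc105R and hdly with the filter at 50.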

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

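Chosen only after the result was seen were the test of shared direction for the third chromosome, the test for wb and Fas3, and the test of ovary tissue in heterozygous fat body replicate 2.

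Genes called between genotypes were concentrated on the third chromosome. Of the third-chromosome calls 0.676% (2 genes) lie within 100 kb of dLmx1a, so the genes beside it do not make up this concentration. A window of that size can hold only a small share of the calls in any case. The value therefore decides nothing about effects of the lesion further away. A candidate explanation is a difference carried by the third chromosomes themselves, TM3 against the chromosome that bears delta1: of the third-chromosome genes called with ovaries 98.3% had the same sign in fat body, although 95.6% of those on other chromosomes did too, so this value does not separate the explanation from others. True regulatory differences and reads lost where a chromosome differs from the reference both stay open, as no sequence was analysed here. Effects of dLmx1a on genes of the third chromosome are confounded with the chromosome and were not tested apart.

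wb was lower and Fas3 higher in fat body with ovaries labelled homozygous. Less ovary tissue in those samples is argued against by the ovary-enriched genes, whose median genotype fold was 0.04 (0.0396, SD over replicates 0.0966) where the wb difference would need a fall. Both genes lie on arm 2L, which was known when they were picked, while hh, lower in the same libraries, lies on arm 3R. Dependence on dLmx1a in the ovary may hold, and so may an indirect effect of the third chromosomes, which differ, and the design gives no test between them. The Fas3 call passed the threshold only with all of the 8 libraries compared, but its fold stayed between 1.47 and 1.71 when any 1 library was left out.

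Ovary transcripts were present at low level in the fat body libraries. In heterozygous replicate 2 the germline genes stood at a median of 7.96% of their level with ovaries (at most 3.46% in the other 7) and the niche genes at 11.5% (at most 8.84%), which is consistent with ovary tissue carried over into that sample. Other ovarian somatic and cell cycle genes were highest in replicate 1 labelled homozygous instead, at 32.2% and 17.5%, and no biological explanation was tested. A weaker tissue contrast of heterozygotes was not shown, since the median interaction of the ovary-enriched genes, 0.11, lay within its spread over replicates. Whether carry-over alone lowers that contrast cannot be told apart from spread. Without replicate 2 the median was -0.02 (-0.0175), which met the outcome written beforehand for carry-over. That outcome was set without regard to the spread over replicates of 0.47, which both medians lie within. The spread itself matches equal replicate numbers across groups, although these did not all pair the tissues of heterozygotes.

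Other splits of the libraries were counted for each comparison. For the tissue contrast of heterozygotes 1 of 35 splits was as large as the real one (2295 genes, highest other split 0). This excludes chance there only if its libraries are unpaired. Replicates 1 and 4 matched best with their own number (0.284 and 0.225), whereas 2 and 3 did not. Among the 8 splits that part all pairs the highest other also called 0. The ovary-enriched genes (839, highest other 0, 1 of 35) are a part of the same calls and give no separate exclusion. In the other 3 comparisons of groups the replicate numbers paired the libraries, and the 8 splits that part all pairs are too few for a share under 0.05. Among those 8 the genotype contrast with ovaries called 165 and the highest other 0, the tissue contrast labelled homozygous 2579 and 0, and the genotype contrast in fat body 422 and 0. The splits that leave pairs together differ in that a difference between replicates can enter them. Over all 35 splits 1 was as large as the real one for the genotype contrast with ovaries (highest other 5) and 1 for the tissue contrast labelled homozygous, where the highest other, which exchanges fat body replicate 1 with replicate 2 with ovaries, called 1831. For the genotype contrast in fat body chance cannot be excluded over all 35 splits, since 2 reached the real 422, the other with 483. That split exchanges heterozygous replicate 1 with replicate 2 labelled homozygous and follows the second principal component, which points to a structure of the samples beyond genotype. With the replicate block the real split called 1178 and the highest other 27. For the interaction 5 of 100 relabellings called at least the real 4 genes, the highest 658, so chance cannot be excluded there, and a relabelling with so many calls points to structure as well. These relabellings were not sorted by whether they part the pairs, so a difference between replicates can enter them too.

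Single libraries stood far from the other 3 of their group in 13 of 288 groups of values, where chance gives about 14.4. Heterozygous fat body replicate 1 had 29.7 M reads (M for mega) against 26.3 to 26.9 M. Argk was at 82.9 normalised counts in heterozygous fat body replicate 2 against 8.91 to 10.8, and bab2 at 70.6 there against 5.66 to 6.68. bab2 was at 982 in heterozygous replicate 2 with ovaries against 1270 to 1334. spn-E was at 1.996 in fat body replicate 4 labelled homozygous against 6.07 to 6.82, and Ect3 at 2192 there against 1002 to 1143. Shaw was at 76.2 in replicate 1 with ovaries labelled homozygous against 111 to 118. Sirt2 was at 70.4 in heterozygous replicate 1 with ovaries against 92.8 to 97.2, and CG42326 at 1556 there against 243 to 305. LysX was at 567 in heterozygous replicate 2 with ovaries against 109 to 135, and Spc105R at 131.5 there against 200 to 211. qin was at 35.6 in heterozygous fat body replicate 3 against 45.0 to 45.3. CR32207 was at 1.21 in fat body replicate 2 labelled homozygous, a value of 1 read, against 0 in the other 3.

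In the main limma fit wb (-3.20), Spc105R (2.97), hdly (1.77) and CR32207 (2.87) passed in the interaction. The value of CR32207 rests on 1 read in the 4 fat body libraries labelled homozygous, and was 3.65 at a pseudocount of 0.5 and 1.20 at 5. None of the 4 genes passed with the replicate number as a block, at a pseudocount of 0.5, without a filter or at equal totals. As given above, chance cannot be excluded for the interaction.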

How the results depend on the processing

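The fits without heterozygous fat body replicate 2 and replicate 1 labelled homozygous, the chromosome test under settings other than a larger fold, and the list counts under the block were chosen after seeing the data. Over all results and alternatives, 2783 values kept their direction and side of the threshold or stayed within 1.5 times a count, 272 calls of single genes or lists were lost, and 95 counts moved further. 0 of these results changed direction past the threshold, but in the full table equal totals turned the sign of the fold of 351 of the 2295 genes called between tissues in heterozygotes and of 478 of the 2579 in the libraries labelled homozygous, and of 0 genes called between genotypes. dLmx1a stayed past the threshold between tissues (log2 fold 6.09 to 8.26 in heterozygotes and 6.76 to 9.14 in the libraries labelled homozygous) and on the other side of it between genotypes under every setting run. The concentration of genotype calls on the third chromosome also passed under every setting run, with odds ratios from 1.95 to 5.65 with ovaries and from 1.62 to 8.38 in fat body. Except where a filter, a threshold or fewer libraries sets it, the cause was not tested. The tissue contrast of heterozygotes (2295 genes) gave 3497 at equal totals, 3531 with the replicate block and 3957 with array weights. The contrast labelled homozygous (2579) stayed within 1.5 times its count. The genotype contrast with ovaries (165) gave 416 with DESeq2, 660 with the block, 725 with array weights, 264 without the pair of fat body libraries that stand apart and 60 to 264 leaving out each library. The genotype contrast in fat body (422) gave 746 with DESeq2, 1178 with the block, 76 with only the 8 libraries compared and 201 to 489 leaving out each library. The interaction (4) gave 0 at a pseudocount of 0.5, 1 without a filter, 0 with the filter at 50, 0 at equal totals, 20 with DESeq2, 0 with the block, 15 with array weights and 0 to 7 leaving out each library. The ovary-enriched genes (839) numbered 488 with the filter at 50, 1274 at equal totals, 515 at 2 log2 units and 355 when chosen on replicates 1 and 2. Of them, 3 passed in the interaction. That number was 0 at a pseudocount of 0.5, 1 without a filter, 0 with the filter at 50, 0 at equal totals, 10 with DESeq2, 0 with the block, 8 with array weights and 0 to 4 leaving out each library. Camera called 9 lists between tissues in heterozygotes (3 with an estimated correlation) and 8 in those labelled homozygous (3, and 11 with fry). It called 2 between genotypes with ovaries (0, 1 with fry, the gut list, 1 without the pair of libraries), 1 in fat body (0, 2 with fry, the neuronal list added) and 0 in the interaction (1 with the block, 1 without the pair of libraries). At 19022106 to 32755588 reads, of which 6 fat body genes take 49.7% to 58.7%, depth limits genes of a few reads per library.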

Other observations

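No explanation was tested in this part, and the Lsp1alpha shares were picked after they were seen.

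RpS5b and RpS19b, paralogues of ribosomal protein genes, were among the few members of their list that were higher with ovaries. RpS5b was at 352 ± 56.1 normalised counts in heterozygous fat body with ovaries against 7.64 ± 12.7 without (SD, n = 4 per group, log2 fold 6.50 ± 0.68, SE, adjusted p = 3.84e-06) and at 376 ± 39.9 against 1.92 ± 0.74 in the libraries labelled homozygous (7.04 ± 0.68). RpS19b was at 193 ± 22.7 against 7.08 ± 3.86 (4.71 ± 0.42) and at 187 ± 30.0 against 1.83 ± 1.70 (6.27 ± 0.42). Their list as a whole had a median of -0.11 and -0.17 between tissues in the deposited normalisation.

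In each group replicate 1 had the highest share of Lsp1alpha, a larval serum protein gene whose product the fat body stores. The shares were 6.70% in fat body labelled homozygous, 4.55% in heterozygous fat body, 4.36% with ovaries labelled homozygous and 2.20% in heterozygotes with ovaries. CG4328, the paralogue of dLmx1a, was at 0 to 4.59 normalised counts in all 16 libraries.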
